A study of Mus musculus with 2 samples.

How the data were processed

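RNA was profiled in 2 libraries of mouse spermatocytes from testis, 1 of Smc1b wild type and 1 labelled as Smc1b knockout overexpressing SMC1alpha. Sample groups were taken from the genotype labels. The sample titles carry "4N", which the labels do not explain. Per the labels' protocols, total RNA was treated with DNase and depleted of ribosomal RNA, strand-specific libraries were made, and single-end reads of 75 bases were sequenced on a NextSeq500 to at least 40000000 reads. Because RNA was not selected for poly(A) tails, small structured RNAs and histone transcripts without tails are part of the total.

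The deposited table gives TPM (share of transcripts) per gene, with 1 column per library that sums to 1000000 over 53801 genes, small non-coding RNAs and ribosomal RNA included. Per the submitters' processing notes, bcl2fastq 2.19.1, GSNAP, kallisto 0.43.1, TopHat and the mm10 build were used. The role and order of these tools, the filters and the annotation release are not given in the sources used here. Per the file headers, the table also holds each gene's length in bases and its G+C content in percent, which describe the gene and not a sample. Of the gene identifiers, 53706 (99.82%) were in the GENCODE M21 annotation of GRCm38, and 97.09% of those had the same start and end there. Coordinates are those of the table. Gene symbols came from the table. Where a symbol occurred more than once (129 entries repeated a symbol already listed), the gene with the higher mean TPM was used for the lists.

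TPM keeps no read counts, so no counting interval or detection limit could be given and no count-based test was run. Because TPM is a share of a total, a gene that takes a larger share lowers all others. A gene at exactly 0 is described as listed at 0 and no fold is given against it. With 1 library per genotype there is no estimate of the spread between animals, and no p-value was computed across genes, which are not replicates. Ratios were log2 of (TPM + 1) in the labelled knockout over (TPM + 1) in wild type, for genes at 1 TPM or more in at least 1 library, and genes were counted at 2-fold. For each of 25 gene lists the median log2 ratio of the members at 1 TPM or more was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and a percentile was given for lists of 5 or more such members. The random lists were drawn from protein-coding genes. The plan did not name a pool, and this one was chosen after seeing that non-coding genes at 1 TPM or more lay lower. Percentiles from lists drawn from all genes were also computed and are given where they change whether a list lies inside the central 95% of random lists. The same was done for the protein-coding genes of each chromosome. The percentiles describe these 2 libraries and are not tests of the genotypes.

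The lists, the measures and the rule for naming genes were fixed before the data were examined. The rule names Smc1b and Smc1a, the other cohesin core genes, the 12 protein-coding genes with the highest and the 12 with the lowest log2 ratio among genes at 5 TPM or more in at least 1 library (clone-type names left out), and in each list up to 4 members furthest in the direction of the median and up to 2 in the other direction. The other settings fixed at the same time were pseudocounts of 0.1 and 5 TPM, rescaling by the trimmed mean of log2 ratios (30% trimmed at each end), rescaling without mitochondrial and the 20 most abundant genes, no filter on low values, a filter of 5 TPM, and counting at 4-fold. Rescaling over protein-coding genes alone was added after seeing the data. A setting that takes 1 transcript per gene could not be run because the table is at gene level.

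The list percentile was tested on simulated data from 21011 genes, in 25 lists per setting. Lists shifted by 1 log2 unit lay above the central 95% of random lists in 92.0% of draws for 10 genes and in 100.0% for 20 genes, and unshifted lists did so in 0.0% and 4.0%. Unshifted lists lay below the central 95% in 4.0% of draws for 10 genes and 8.0% for 20 genes. The simulated genes varied independently, included non-coding genes and were filtered on mean TPM. Members of the real lists can vary together, their pool was protein-coding, and their filter used the library with the higher value. These rates therefore do not carry over to the percentiles reported here. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.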

Results

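RNA was measured in mouse spermatocytes, the germ cells that carry out meiosis, sorted from testis. One library came from Smc1b wild-type cells and 1 from cells labelled as Smc1b knockout with SMC1alpha overexpression, so each genotype had 1 library. Cohesin is the ring-shaped complex that holds sister chromatids together. SMC1beta is its meiosis-specific SMC1 subunit and SMC1alpha is the form found in all cells. The labels frame the series around how the functions of the 2 forms separate. A knockout without added SMC1alpha was not analysed here, so loss of the one form and gain of the other are not separated in this comparison. The table listed 53801 genes in TPM, a share of all transcripts. It held 20222 genes at 1 TPM or more in the wild-type library and 20492 in the labelled knockout. The labels ask for at least 40000000 reads per library, and the table itself holds no read counts, so the depth behind each value is unknown. With no replicates, no difference below has a replicate check, no p-value is given, and "higher" and "lower" describe these 2 libraries only. Ratios are log2 of (TPM + 1) in the labelled knockout over (TPM + 1) in wild type, which understates differences of low genes.

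Smc1b, the gene named as deleted, was still detected in the library labelled knockout. Smc1b (ENSMUSG00000022432; mm10 chromosome 15, 85064689 to 85131964, minus strand) stood at 76.1 TPM in wild type and 62.9 TPM in the labelled knockout, which is 82.7% of the wild-type value. Its log2 ratio was -0.27 as deposited and lay between 0.019 and 0.13 after 3 kinds of rescaling, so its direction depends on the scaling. TPM summed over all transcripts of a gene cannot show whether a deleted part of Smc1b is present, so this value neither bears out the label nor excludes it, and the library is called "labelled knockout" throughout. Smc1a (ENSMUSG00000041133; mm10 chromosome X, 152016428 to 152062694, plus strand), the gene named as overexpressed, stood at 0.51 TPM in wild type and 28.75 TPM in the labelled knockout, 56.4-fold higher (log2 ratio 4.30). Among 620 X-linked protein-coding genes, 2 had a higher log2 ratio than Smc1a, which put it at the 99.5th percentile. The table cannot tell transcripts of the native Smc1a gene from those of an added copy.

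Among the other cohesin subunits, those shared with mitotic cells were higher in the labelled knockout and those of the meiotic complex were mixed. Of the shared ones, Stag2 was 3.25-fold higher, while Stag1 (1.89-fold), Rad21 (1.5-fold) and Smc3 (1.39-fold) stayed below 2-fold. Stag2 stood at 4.10 TPM in wild type and 13.33 TPM in the labelled knockout, and Stag1 at 27.27 and 51.58 TPM. Rad21, the general kleisin subunit, stood at 10.95 and 16.4 TPM, and Smc3, the partner of both SMC1 forms, at 12.67 and 17.57 TPM. Stag2 is X-linked, and X-linked genes and markers of spermatogonia, Sertoli and Leydig cells, described below, were also higher in the labelled knockout. The meiotic kleisins went opposite ways, with Rad21l at 0.136 and 5.82 TPM and Rec8 at 13.88 and 5.17 TPM. Stag3, the meiotic STAG subunit, was the most abundant at 303.7 TPM in wild type and 199.1 TPM in the labelled knockout. The 9 core genes had a median log2 ratio of 0.54, at percentile 94.7 of 10000 random lists of protein-coding genes matched on expression and 98.0 of lists drawn from all genes, so whether the list lies outside the central 95% of random lists depends on the pool. The 16 cohesin regulators had a median of -0.13 at percentile 66.6, and this median turned positive under each rescaling. Nipbl, the cohesin loader, stood at 198.4 and 66.7 TPM and Espl1, the protease separase, at 84.28 and 29.71 TPM. Sgo1, a protector of centromeric cohesin, stood at 0.93 and 4.57 TPM and Esco2, a cohesin acetyltransferase, at 7.15 and 20.34 TPM.

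**Figure D1:**
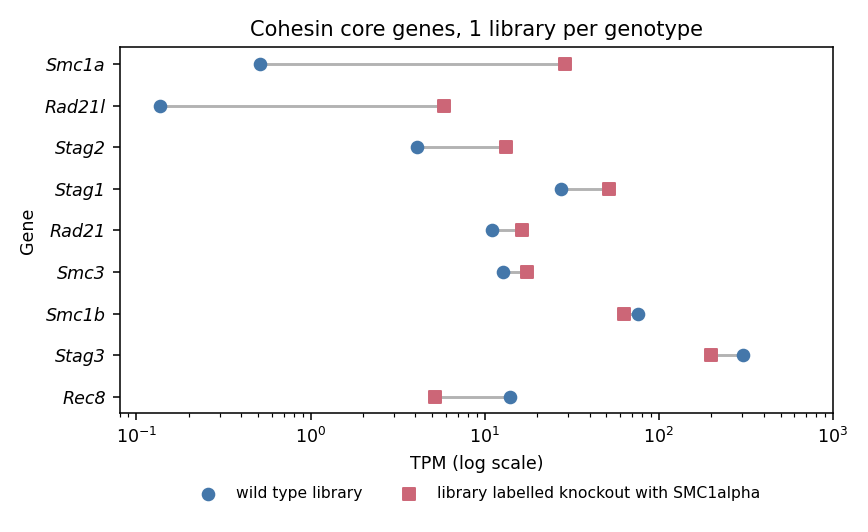
TPM of the 9 cohesin core genes on a logarithmic axis, with circles for the wild-type library and squares for the library labelled knockout (1 library each, no error bars). Smc1a and Rad21l are furthest apart, and Smc1b lies at 76.1 and 62.9 TPM.

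Across the transcriptome, genes differed in both directions. Of 23148 genes at 1 TPM or more in at least 1 library, 3478 were at least 2-fold higher in the labelled knockout and 4468 at least 2-fold lower. The median of all these genes was -0.22, against -0.05 for the 15000 protein-coding genes, of which 2803 were higher and 2479 lower. The all-gene median moved to 0.05 after rescaling by the trimmed mean and to 0.17 after leaving out mitochondrial and the 20 most abundant genes. The split of higher against lower turned with it, to 4703 against 3254 of 23814 genes and to 6131 against 3314 of 26268 genes. Rescaling also changes which genes reach 1 TPM, so these counts come from other gene sets. Rescaling protein-coding genes alone moved their median to 0.32 and their split to 4487 against 1748 of 16496 genes. Abundant small RNAs took a larger share in the labelled knockout. The 7SL RNAs, part of the signal recognition particle, held 21.2% of all TPM in wild type and 32.7% in the labelled knockout, and protein-coding genes held 62.6% and 49.0%. Other abundant untranslated RNAs, named after their values were seen, were also higher in the labelled knockout, among them Rpph1, the RNA of RNase P (3.44-fold), the ribosomal RNA gene CT010467.1 (2.33-fold) and Rn7sk (1.47-fold). So were Gm26917 (3.45-fold) and AL732506.1 (4.44-fold), which are classed as lincRNA.

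The 12 genes with the lowest log2 ratios included the protamines and transition proteins, which replace histones in sperm chromatin. Prm1 stood at 1004 TPM in wild type and 9.15 TPM in the labelled knockout, Prm2 at 530.1 and 6.39 TPM, Tnp1 at 430.2 and 8.22 TPM, and Tnp2 at 266.5 and 5.92 TPM. Grtp1 stood at 210.8 and 2.58 TPM and Iqcf3 at 81.52 and 3.67 TPM. Akap4, a scaffold of the sperm tail sheath, stood at 91.86 and 4.70 TPM, and the histone variant gene H2afb1 at 29.67 and 0.53 TPM. Cabs1, Tppp2, Spem1 and Spata3 had log2 ratios of -4.93, -4.33, -4.31 and -4.12. Among the 12 highest were Insl3, a Leydig cell hormone, at 43.25 TPM in wild type and 1352 TPM in the labelled knockout, and Hsd3b6, a steroid dehydrogenase, at 2.06 and 66.39 TPM. Sult1e1, an oestrogen sulfotransferase, stood at 0.20 and 27.28 TPM, Apoc1 at 0.29 and 43.34 TPM, Lcn2 at 7.62 and 230.8 TPM, and the adhesion molecule gene Vcam1 at 4.08 and 102.9 TPM. Lars2 stood at 5.68 and 259.6 TPM, a log2 ratio of 5.29. The histone genes Hist1h2ak, Hist1h2bl, Hist1h3i and Hist1h2ah had log2 ratios of 4.85, 4.61, 4.57 and 4.45, and Hist1h2ap was listed at 0 in wild type and stood at 27.16 TPM in the labelled knockout. Histone genes share near-identical sequences, so the values of single members are uncertain.

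Genes of early meiotic prophase were higher in the labelled knockout. The 10 genes of the synaptonemal complex and chromosome axis, the structure that joins homologous chromosomes, had a median log2 ratio of 1.21, which was 1.25 above the protein-coding median and at percentile 100. Of these, 7 were at least 2-fold higher and 0 at least 2-fold lower. Sycp1, the central transverse filament, stood at 68.36 TPM in wild type and 259.4 TPM in the labelled knockout, Tex12 at 16.29 and 57.87 TPM, 4930447C04Rik (Six6os1) at 21.54 and 90.72 TPM, and Hormad2 at 36.82 and 96.14 TPM. Syce1 was lower, at 239.4 and 132.6 TPM. Sycp2 had a log2 ratio of -0.11, which turned positive under each rescaling. The 17 genes of meiotic entry and leptotene, 10 of them also in other lists, had a median of 1.18 at percentile 100, with 10 higher and 2 lower. Stra8, which drives entry into meiosis, stood at 0.165 and 9.70 TPM, and Scml2 at 3.22 and 38.9 TPM. Dmrtb1 went the other way, at 361.7 and 87.9 TPM. The 24 genes of recombination and crossover formation had a median of 0.53 at percentile 99.9, with 10 higher and 1 lower. Dmc1, the meiotic recombinase, stood at 0.78 and 21.27 TPM, Tex11 at 0.36 and 12.22 TPM, Rad51ap2 at 0.54 and 13.05 TPM, and Mnd1 at 1.42 and 15.64 TPM. Prr19 and 4930432K21Rik (Brme1) were lower, with log2 ratios of -1.42 and -0.90. The 9 measured genes of double-strand break formation did not stand apart, with a median of -0.04, a mean of 0.29 and percentile 59.8, and the median turned positive under each rescaling. Hormad1 stood at 167.9 and 395.4 TPM and Gm960 (Top6bl) at 1.94 and 7.75 TPM, while Rec114 and Ccdc36 (Iho1) had log2 ratios of -0.87 and -0.70. Spo11, the enzyme that makes the breaks, stood at 102.2 and 79.35 TPM, with a direction that turned under 1 rescaling, and Mei1 had a log2 ratio of -0.04 that turned under each. Markers of spermatogonia, described below with the other cell types, were higher in the same library.

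Most listed genes of late prophase and of sperm formation were lower in the labelled knockout. The 30 late pachytene and diplotene genes had a median log2 ratio of -1.18, which was -1.14 relative to the protein-coding median and at percentile 0.0, with 18 at least 2-fold lower and 1 higher. Ccna1, the cyclin of the meiotic divisions, stood at 185.6 TPM in wild type and 38.04 TPM in the labelled knockout, Pou5f2 at 92.82 and 15.16 TPM, Cst8 at 23.83 and 3.88 TPM, and Adam3 at 568.0 and 139.5 TPM. Of the 30 genes, 27 were lower, while Tex101, Hist1h1t and Tesmin were higher, with log2 ratios of 1.40, 0.52 and 0.235. Among the 27, Sox30, Mybl1 and Piwil1 had ratios of only -0.10, -0.23 and -0.42. Whether RNA of spermatids contributes to the higher wild-type values of this list was not settled, as described below. The 21 genes of the meiotic divisions had a median of -0.74 with 7 lower and 2 higher, at percentile 3.24 and inside the range of random lists. Plk1 stood at 67.28 and 15.71 TPM, Aurkc at 49.35 and 12.66 TPM, and Aurkb at 29.19 and 7.93 TPM, while Ccnb3 (0.279 and 7.54 TPM) and Mad2l1 (13.99 and 30.94 TPM) were higher. The 30 round and elongating spermatid genes had a median of -2.59 at percentile 0.0, with 29 at least 2-fold lower and 0 higher. Their TPM summed to 3555 in wild type and 292.5 in the labelled knockout. Most late prophase genes and the markers of this later cell type were thus higher in the same library, that of wild type.

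**Figure D2:**
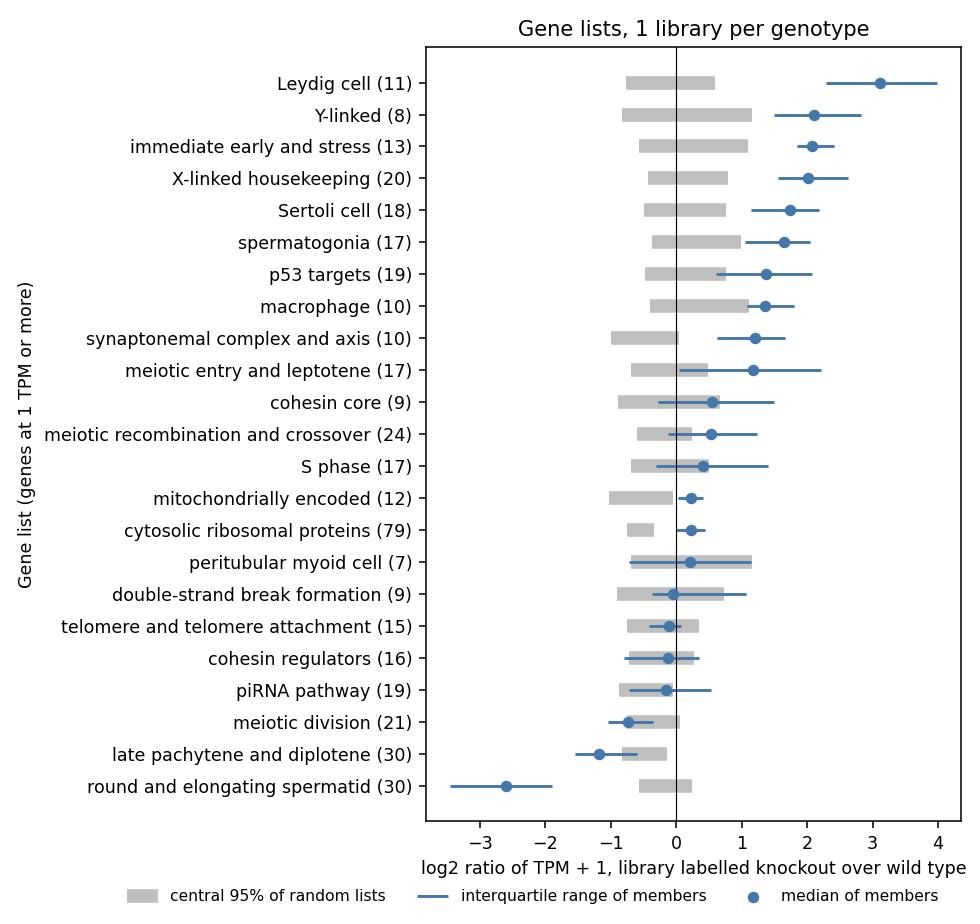
Median log2 ratio of each gene list with 5 or more members at 1 TPM (points), the interquartile range of its members (lines) and the central 95% of random lists matched on expression (grey bars), for 1 library per genotype. Spermatid genes lie lowest at -2.59 and Leydig cell genes highest at 3.11; medians close to 0 (cohesin regulators, double-strand break formation, telomere, piRNA) turn positive when the libraries are rescaled.

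Markers of testis cells other than spermatocytes differed between the libraries, and most were higher in the labelled knockout. The 11 Leydig cell genes had a median log2 ratio of 3.11 at percentile 100, with 9 higher and 0 lower, and summed to 135.1 TPM in wild type and 1780 TPM in the labelled knockout. Cyp17a1, a steroid hydroxylase, stood at 5.65 and 101.7 TPM and Hsd3b1 at 1.30 and 35.88 TPM. The 18 Sertoli cell genes had a median of 1.74 at percentile 100, with 15 higher and 0 lower, among them Clu (30.71 and 220.5 TPM), Defb19 (20.45 and 123.5 TPM), Aard (8.69 and 50.42 TPM) and Cldn11 (2.02 and 17.17 TPM). The 17 spermatogonia genes, which mark the germ cells before meiosis, had a median of 1.64 at percentile 100, with 13 higher and 0 lower. Sohlh2 stood at 1.04 and 21.09 TPM, Dmrt1 at 0.79 and 7.21 TPM and Sall4 at 0.0688 and 4.15 TPM. Rhox13 was listed at 0 in wild type and stood at 6.32 TPM in the labelled knockout, and Gfra1 had a log2 ratio of -0.17, with a direction that turned under 2 of the 3 rescalings. The 10 macrophage genes had a median of 1.36 at percentile 99.9, led by Lyz2 at 0.79 and 13.76 TPM. C1qc stood at 0.0446 and 2.12 TPM, C1qa and Fcer1g were listed at 0 in wild type and stood at 2.65 and 4.32 TPM, and Cx3cr1 was lower at 1.83 and 1.01 TPM. The 7 peritubular myoid genes went both ways, with a median of 0.22 at percentile 45.3. Dcn stood at 6.48 and 41.0 TPM, Des at 0.152 and 1.58 TPM, Acta2 at 0.30 and 1.84 TPM and Cnn1 at 0.77 and 1.05 TPM, while Actg2 stood at 19.68 and 2.78 TPM and Mylk at 19.07 and 6.93 TPM. Too few endothelial (3) and red blood cell (4) genes reached 1 TPM for a percentile, and their medians were 0.04 and 0.53. Pecam1, Egfl7 and Vwf had log2 ratios of 0.15, 0.04 and -0.21, and that of Vwf turned positive under each rescaling. Hbb-bs, Hba-a2 and Alas2 had ratios of 1.08, 0.61 and 0.43, and Hba-a1 one of -0.09 that turned under each rescaling.

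X-linked genes were higher in the labelled knockout as a chromosome-wide group. The sex chromosomes are silenced in pachytene spermatocytes, which is why they were examined separately. The 620 X-linked protein-coding genes had a median log2 ratio of 1.30, against an interval of 0.26 to 0.50 for random lists matched on expression, and 83.5% of them were higher. Of these genes, 389 were at least 2-fold higher and 37 at least 2-fold lower, and the median X-linked gene stood at 1.05 TPM in wild type and 3.96 TPM in the labelled knockout. The medians of the 19 autosomes lay between -0.19 and 0.0045, and the X median was 1.38 above that of the autosomal genes. The 20 X-linked housekeeping genes had a median of 2.02 at percentile 100, with 18 at least 2-fold higher and 0 lower. Fmr1 stood at 2.80 and 57.43 TPM, Ddx3x at 1.47 and 21.39 TPM, Huwe1 at 5.56 and 45.74 TPM, and Hprt, a purine salvage enzyme, at 0.49 and 13.2 TPM. The 8 listed Y-linked genes at 1 TPM or more had a median of 2.10 at percentile 99.98, among them Zfy1 (0.60 and 13.96 TPM), Zfy2 (1.03 and 17.24 TPM), Usp9y (1.22 and 13.62 TPM) and Uba1y (3.19 and 20.17 TPM). Kdm5d stood at 7.01 and 6.78 TPM, a log2 ratio of -0.04 that turned positive under each rescaling. All 81 Y-linked protein-coding genes together had a median of -0.04 at percentile 1.20. Many of these belong to multicopy families whose reads are shared between near-identical copies. Sertoli, Leydig, macrophage and spermatogonia markers were higher in the same library as the X-linked genes.

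**Figure D3:**
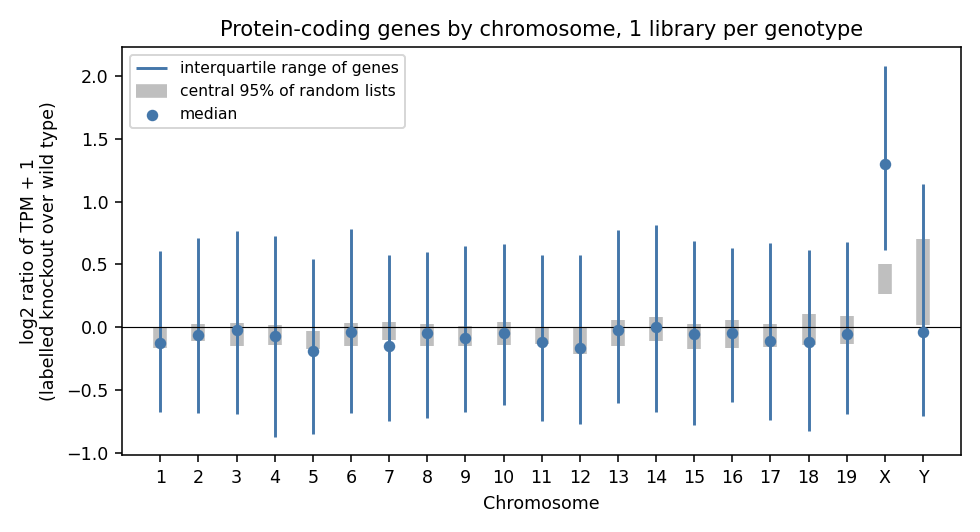
Median log2 ratio of protein-coding genes at 1 TPM or more on each chromosome (points), their interquartile range (lines) and the central 95% of random gene lists matched on expression (grey bars), for 1 library per genotype. The X chromosome lies at 1.30 and the 19 autosomes between -0.19 and 0.0045.

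Stress-related genes were higher in the labelled knockout, in the same library as the Leydig, Sertoli, macrophage and spermatogonia markers. The 13 immediate early and stress genes had a median log2 ratio of 2.07 at percentile 100, and 13 of 13 were at least 2-fold higher. Fos stood at 5.56 TPM in wild type and 48.62 TPM in the labelled knockout, Junb at 2.71 and 23.29 TPM, and Fosb at 2.70 and 18.69 TPM. The 19 genes activated by p53 had a median of 1.37 at percentile 100, with 12 higher and 1 lower. Pmaip1, which encodes the apoptosis protein NOXA, stood at 1.74 and 32.28 TPM, Btg2, which is in both lists, at 0.96 and 11.95 TPM, Ddit4 at 0.48 and 7.78 TPM, and Ei24 at 8.90 and 43.46 TPM. Zmat3 was lower at 20.59 and 7.32 TPM, and Aen stood at 22.71 and 17.41 TPM with a direction that turned under 1 rescaling.

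The remaining lists lay closer to the random lists or differed by less. The 19 piRNA pathway genes had a median log2 ratio of -0.15 and a mean of 0.01, at percentile 92.4, and the median turned positive under each rescaling. Tdrd6 stood at 387.3 and 122.2 TPM, and Ddx25, Henmt1 and Tdrd7 had log2 ratios of -1.21, -1.08 and -0.86, while Btbd18 stood at 1.00 and 12.21 TPM and Tex19.1 at 5.40 and 29.47 TPM. The 15 telomere genes had a median of -0.11 at percentile 65.1, which also turned positive under each rescaling. Terf2, Terb1, Terf1 and Spdya had log2 ratios of -1.08, -1.07, -0.93 and -0.43, and Pot1a and Terb2 had ratios of 0.83 and 0.56. The 17 S phase genes had a median of 0.41 at percentile 95.6 of protein-coding lists and 99.2 of lists from all genes. This median turned to -0.074 with genes at 5 TPM or more. The replication helicase genes Mcm4, Mcm5, Mcm2 and Mcm3 had log2 ratios of 2.10, 2.02, 1.94 and 1.55, and Cdc6 and Rrm2 had ratios of -1.24 and -0.81. The 12 mitochondrially encoded genes had a median of 0.23 at percentile 99.9, against -1.02 to -0.05 for random lists, with 0 of them differing 2-fold. mt-Cytb stood at 587.8 and 1087 TPM, mt-Nd4, mt-Nd1 and mt-Nd2 had log2 ratios of 0.50, 0.46 and 0.39, and mt-Co2 and mt-Nd3 had ratios of -0.11 and -0.03 that turned positive where a rescaling kept mitochondrial genes. The 79 ribosomal protein genes had a median of 0.23 at percentile 100, against -0.75 to -0.33 for random lists, with 9 higher and 1 lower. The highest were Rpl10, Rps4x, Rpl39 and Rpl36a, each X-linked, with log2 ratios of 2.74, 2.58, 2.17 and 1.88, and Rpl26 and Rpl29 had ratios of -1.04 and -0.96.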

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

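The Smc1b and Smc1a ratios, the counts of genes, the medians of lists given a percentile, the X chromosome median and the named genes were recomputed under the alternatives that apply to them, and the 4-fold setting applies to the counts alone. Percentiles among random lists, the medians of the endothelial and red blood cell lists, of autosomes and of the Y chromosome, the fit of GC content and the quartile gaps between lists were not. Rescaling over protein-coding genes alone was chosen after seeing the data. Of the 23 lists given a percentile, 14 had medians above 0 and 3 (late pachytene and diplotene, meiotic division, spermatid) below 0 under each alternative that gave a value, and 6 took both signs. Smc1a ranged from 2.62 to 5.56 and the X chromosome median from 0.51 to 2.24. The transcript with the highest TPM per gene could not be used because the table is at gene level, and mitochondrial genes have no value where they are left out. No paired analysis was possible because each genotype has 1 library. The table holds no counts, so what depth limits is unknown. Except where stated, the cause of a difference between settings was not tested.

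At 4-fold, 833 genes were higher and 779 lower. With genes at 5 TPM or more, 1942 were higher, the X median was 2.10 and the macrophage median 3.04, while the myoid (-1.34) and S phase (-0.074) medians changed sign over fewer genes. With no filter, the X median was 0.68 and the break formation median 0.24, which changed sign. With a pseudocount of 0.1 TPM the values were 5.56 for Smc1a, 2.97 for spermatogonia, 4.12 for Leydig, 2.80 for macrophage, 2.66 for X-linked housekeeping, 2.72 for immediate early genes and 2.24 for X. With 5 TPM they were 2.62 for Smc1a, -1.66 for spermatid, 0.64 for spermatogonia, 1.11 for Sertoli, 2.29 for Leydig, 0.49 for macrophage, 1.11 for X-linked housekeeping, 0.63 for p53 targets, 0.97 for immediate early genes and 0.51 for X, with 1144 genes higher and 2189 lower (32.9% and 49.0% of the original sets).

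With the trimmed mean, signs changed for Smc1b (0.019), cohesin regulators (0.14), break formation (0.25), piRNA (0.14), telomere (0.18), Sycp2 (0.19), Mei1 (0.17), Vwf (0.0044), Hba-a1 (0.074), Kdm5d (0.22), mt-Co2 (0.18) and mt-Nd3 (0.27). Without mitochondrial and the 20 most abundant genes, they changed for Smc1b (0.13), cohesin regulators (0.25), break formation (0.63), piRNA (0.26), telomere (0.29), Sycp2 (0.30), Spo11 (0.043), Mei1 (0.28), Gfra1 (0.077), Vwf (0.10), Hba-a1 (0.16), Kdm5d (0.33) and Aen (0.024); Smc1a was 5.02, immediate early genes 2.68, and 6131 genes were higher. With protein-coding genes rescaled alone, they changed for Smc1b (0.078), cohesin regulators (0.21), break formation (0.61), piRNA (0.21), telomere (0.24), Sycp2 (0.25), Mei1 (0.24), Gfra1 (0.040), Vwf (0.054), Hba-a1 (0.13), Kdm5d (0.28), mt-Co2 (0.24) and mt-Nd3 (0.33); Smc1a was 5.04, immediate early genes 2.70, and 1748 genes were lower. This setting changes the gene set as well as the scaling, and before rescaling 2479 protein-coding genes were lower. Smc1b changed sign under each rescaling.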

Other observations

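The gene groups in this paragraph and the next were chosen after seeing the data. Replication-type and testis histone genes were higher in the labelled knockout as a family: 65 genes had a median log2 ratio of 2.44, with 53 at least 2-fold higher and 3 lower, and the family median stayed between 1.71 and 2.92 under the alternatives. Together they held 0.69% of protein-coding TPM in wild type and 3.0% in the labelled knockout. Hist1h2ba, a testis-specific H2B gene, stood at 2013 TPM in wild type and 7101 TPM in the labelled knockout, and Hist1h4h at 261.8 and 1190 TPM, while Hist2h2aa1 stood at 594.1 and 268.9 TPM and its near-identical copy Hist2h2aa2 at 44.18 and 542.7 TPM. In the same library spermatogonia markers were higher (median 1.64), while the S phase list, with 9 of 17 genes higher, had a median of 0.41 that lay inside the range of random protein-coding lists and turned to -0.074 at 5 TPM or more. The abundant untranslated RNAs Rpph1, CT010467.1 and Rn7sk were 3.44-fold, 2.33-fold and 1.47-fold higher. The 108 genes classed as miscellaneous RNA, Rn7sk among them, had a median of -0.20, with 24 higher and 31 lower. The largest classes of long non-coding genes lay lower than coding ones, with a median of -0.60 for 2090 lincRNA genes and -0.51 for 1351 antisense genes against -0.05 for protein-coding genes. With a pseudocount of 5 TPM these medians were -0.28, -0.23 and -0.03, and with no filter on low values they were 0.0, -0.07 and 0.0. The contrast was wider with a pseudocount of 0.1 TPM (-0.82, -0.72 and -0.05) and with genes at 5 TPM or more (-0.90, -0.90 and -0.18). Its size thus depends on how low genes are treated. The Klk1b kallikrein genes, neighbours on chromosome 7 with similar sequences, were higher in 5 of 7 cases, for example Klk1b24 at 0.41 and 16.41 TPM, and Klk1b21 was listed at 0 in wild type and stood at 18.5 TPM in the labelled knockout. Leydig and Sertoli markers, with medians of 3.11 and 1.74, were higher in the same library.

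X-linked genes differed from autosomal genes of the same function. The 4 X-linked ribosomal protein genes had log2 ratios of 1.88 to 2.74, each above the highest of the 75 autosomal ones (1.35), whose median was 0.19. With a pseudocount of 5 TPM, 3 of the 4 were. The 2 groups were not matched on expression, with a median of 4.96 TPM in wild type for the X-linked and 248 TPM for the autosomal genes. Several X-linked genes have an autosomal retrogene copy that is active in meiosis. In 9 such pairs, chosen from memory with some of their values already seen, the X-linked gene was higher in the labelled knockout in 9 and had the higher log2 ratio of its pair in 9, under each alternative. The autosomal copy was lower in 8 of 9, and in 6 of 9 under each of the 3 rescalings. For comparison, 83.5% of all X-linked protein-coding genes were higher as reported. Rpl10, Rpl39 and Rpl36a are among the ribosomal protein genes above. Pgk1, Pdha1 and Utp14a are in the X-linked housekeeping list, and Pgk2 and Cetn1 are in the late pachytene list. The pairs are thus not independent of those results. Cetn2 on the X chromosome stood at 0.99 and 13.11 TPM and its copy Cetn1 at 271.1 and 98.55 TPM. Pgk1 stood at 9.03 and 13.91 TPM and Pgk2 at 209.3 and 58.19 TPM. Reads can be shared between the members of such pairs.

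Of the tests below, the one on GC content and gene length was planned before its result was seen, and the others were chosen after the results were seen. Smc1a was higher in the labelled knockout and lay at percentile 99.5 of the X-linked protein-coding genes, and between 98.9 and 99.7 under the alternatives. A general X-linked difference has a spread. As reported, 2 X-linked genes had a higher log2 ratio than Smc1a, and 5 did with a pseudocount of 0.1 or 5 TPM. Smc1a was also low in wild type, at 0.51 TPM, so its high rank does not exclude a general X-linked difference. RNA of other cells that carry Smc1a would raise ubiquitous X-linked genes as much. As reported, 0 of the 20 X-linked housekeeping genes had a log2 ratio as high, the highest being Fmr1 at 3.94, but with a pseudocount of 5 TPM 1 did, Fmr1 at 3.001 against 2.615 for Smc1a, so this explanation stays open. Added Smc1a expression, as the label states, also stays open with 1 library per genotype.

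X-linked genes as a group were higher in the labelled knockout. RNA of somatic cells alone would leave X-linked genes of germ cells within the range of random lists (up to 1.08), and 12 such genes, listed after seeing the data, had a median log2 ratio of 2.72, with Tex13a going the other way at -1.53. Of these, 3 (Tex11, Scml2 and Rhox13) were also in other lists, and the other 9 had a median of 2.59 against a range of random lists up to 1.25. Spermatogonia markers (median 1.64) had already been seen higher, so this outcome could be foreseen. The germ-cell genes were not split into those of spermatogonia and those of spermatocytes. Their values thus speak only to RNA of somatic cells alone. Scaling by abundant small RNAs would shift X-linked and autosomal genes alike, and their medians lay 1.38 apart, and a fit of GC content, gene length and mean expression on autosomal genes left an X-linked median of 1.08, outside the range of random autosomal lists (-0.0933 to 0.0924). RNA of spermatogonia, in which the X chromosome is active, may account for it and cannot be told apart, since the X-linked median of 1.3 lies below the upper quartile of the spermatogonia markers (2.05). Weaker silencing of the X chromosome in the genotype and a larger share of cells before pachytene, as the early and late prophase lists would also allow, stay open and untested.

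Markers of Leydig, Sertoli and macrophage cells were higher in the labelled knockout. The myoid genes (median 0.22) lay inside the range of random lists, and the 3 endothelial genes had a median of 0.04. A lower share of spermatocytes alone would raise the somatic cell types alike. As reported, the lower quartile of the Leydig genes (2.29) lay above the upper quartiles of the Sertoli (2.18), macrophage (1.8) and myoid (1.15) genes. The gap to the Sertoli genes was 0.11, and no gap was recomputed under the alternatives, so this explanation is not excluded. The gap to the spermatid genes was 4.18 log2 units. Spermatids are a later stage of the same cells and their lower values had been seen, so that gap cannot decide. Scaling by abundant small RNAs, which took a larger share of the labelled knockout, went the opposite way, with a trimmed mean log2 ratio of -0.29 over 17566 genes. Carry-over of Leydig and Sertoli RNA into the labelled knockout library, which sorting should reduce, remains a candidate explanation, with Insl3 at 1352 TPM and Clu at 220.5 TPM there. It cannot be separated from genotype with 1 library each.

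For the lower late pachytene genes, RNA of spermatids in the wild-type library was tested on the meiotic division list, whose percentile of 3.24 decided neither way. Of its 21 genes, 4 (Ccna1, Aurkc, Nek2 and Cdc25c) are also in the late pachytene list and were lower, so the test rested partly on the same values.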
